A study of Drosophila melanogaster with 8 samples.

How the data were processed

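Brains of wandering, last-instar larvae with the genotypes repo>+ and repo>AmaRNAi were each represented by 4 Drop-seq libraries. Per the labels' protocols, brains were dissociated with trypsin and collagenase, cells were run through the Drop-seq protocol, and libraries were tagmented with Nextera XT. Per the submitters' processing notes, read quality was examined with FastQC and reads were aligned to BDGP6 with STAR, without versions. The deposited tables hold raw counts per gene and cell barcode, called UMIs here. The counting tool, the collapsing of UMIs and the gene annotation are not given in the sources used here. The number of animals per library is not given either.

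The tables held 23831 to 23986 barcodes per library and 13574 genes in all, of which 13525 had symbols found among the symbols and synonyms of the RefSeq gene table. Gene identifiers and locations were taken from the Ensembl annotation of BDGP6.54, a later release than the one named for the files. Barcodes were kept as cells with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Scrublet as included in scanpy 1.11.5 marked 29 cells (0.191%) as doublets with its automatic threshold. As this was under 0.5%, the 5% of cells with the highest scores were removed from each library, by the rule set before the data were examined. Cells with under 300 genes, and with them most barcodes, were left out of the class comparisons. Barcodes with under 100 UMIs held 9.05 to 12.8% of counts in control and 9.12 to 19.8% in knockdown libraries, and served as a measure of free RNA.

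Counts of retained cells were scaled to the same total, log-transformed and reduced to 1500 variable genes and 30 principal components. A graph of 15 neighbours was clustered with the Leiden algorithm at resolution 1.5 (seed 0), and glia again at 0.6 for subtypes. Variable genes were chosen within libraries, without Ama, mitochondrial, roX, ribosomal RNA and heat shock genes, and no batch correction was applied. Each cluster was named from fixed marker lists (11 for classes, 6 for glial subtypes, 17 in all). A class needed at least 3 markers with at least 10 UMIs and a log2 ratio of at least 0.5 over the other cells, at least 50% of its list, and a mean log2 ratio of at least 0.3. A cluster stayed unnamed where its 10 leading genes held more markers of another class (for glial subtypes only of another subtype), or where its cells were shallow and no own marker led. These thresholds, the offset of 20 CPM in the ratios and the removal of cells with ring gland markers from glia were set after the clusters had been seen. The marker lists, cell filters, tests, gene lists and the rule for naming genes were set before the data were examined. Of 27 clusters 24 were named. The 3 unnamed clusters, kept out of the classes, held 5.36, 1.12 and 1.51% of control and 0.60, 0.020 and 3.55% of knockdown cells. From glia, 2 cells with at least 2 UMIs of ring gland markers were removed. The 10 leading genes of each cluster were listed so that gene results could be set beside them.

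UMIs were summed per library and class, and the 4 control and 4 knockdown sums were compared with the quasi-likelihood F test of edgeR 4.0.16 (filterByExpr by group, TMM normalisation). Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. CPM of gene values are TMM-normalised, whereas CPM over all barcodes or over barcodes with under 100 UMIs are raw counts over the total. The difference between glia and neurons was tested as the interaction of class and genotype with the library as a term. Comparisons of newborn neurons and neuroepithelium were added after the data had been seen. Shares of classes and glial subtypes were compared with exact two-sided permutation tests over the 70 relabellings of 8 libraries. Beside a group with 0 counts a floor of 3 counts over that group was used, and for 1 to 3 counts an exact 95% counting interval of the ratio.

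Genes were named by a rule. In glia these were the 8 largest increases and 8 largest decreases among changed genes with a mean of at least 50 CPM and no overlap of library values between groups, and up to 4 genes of each list with the smallest adjusted p. In neurons and in neuroblasts they were 6 each way and up to 2 changed genes per list, in all cells 5 each way, and in the interaction 5 each way. Ama, sty and repo were always considered. Of these genes the report prints mainly those whose call did not depend on a single library. Gene lists were fixed for 21 groups. They were RTK targets and feedback genes, RTK receptors and cascade, RTK ligands, cell cycle, cell death, JNK and wound response, heat shock, immune effectors, septate junction, engulfment and basement membrane. The others were glutamate handling, glycolysis, lipid handling, ecdysone response, Notch targets, synaptic genes, mitochondrially encoded genes, glutathione, unfolded protein stress and immunoglobulin-domain partners. Lists with at least 3 tested members were tested with camera (limma 3.58.1) with the preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a class.

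The scripts were tested on simulated counts with the depth of the real sums and 200 changed genes. At 2-fold and 4-fold changes the test recovered 58 and 97% of changed genes in glia (6 of 161 calls false), 59 and 98% in neurons (3 of 160) and 61 and 99% in neuroblasts (7 of 167). It recovered 61 and 98% over all cells (5 of 164), and 20 and 71% for the interaction (3 of 94). About 40% of true 2-fold changes within a class would thus be missed. Alternatives were DESeq2 1.42.0 size factors and its Wald test, no count filter, the replicate number as a block, each library left out and, for the interaction, limma voom with the library as a random block. Others were 200 or 600 genes per cell without a UMI minimum, doublet calls kept, classes from marker UMIs alone (at least 2 UMIs), and clustering at resolutions of 0.75 and 3. Leaving out the perineurial-like glia, using only clusters with at least 5 cells in every library, and leaving out the 2 shallowest libraries were added after seeing the data. Further tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.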

Results

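Single-cell RNA sequencing by Drop-seq, which captures single cells with barcoded beads in droplets and reads one end of each messenger RNA, was applied to dissociated brains of wandering, last-instar larvae of Drosophila melanogaster. The study compared 4 control libraries with 4 libraries in which Amalgam (Ama) was targeted by RNA interference in glia. Control animals carried the driver repo-GAL4 alone (repo>+), which is active in glia because it uses the promoter of the glial gene repo. Knockdown animals carried the same driver and an Ama RNAi construct, which makes double-stranded RNA against the Ama transcript. Ama encodes a secreted protein with immunoglobulin domains that binds the membrane protein Neurotactin. Total counts of control replicates 1 to 4 were 3333735, 5774598, 5488489 and 6150916. Those of knockdown replicates 1 to 4 were 1443793, 1647443, 3476992 and 5647367, so the 2 shallowest libraries were both knockdowns. After filtering, 1569, 2728, 2683 and 3047 control cells and 307, 479, 1244 and 2384 knockdown cells were kept, with library medians of 852 to 978 unique molecular identifiers (UMIs) per cell. The median mitochondrial share per cell was 1.38 to 1.96% in control and 1.78 to 3.53% in knockdown libraries. The labels do not say that libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Replicate libraries differed from each other by more than sampling noise in all 12 pairs, with chi-square values of 6.24 to 53.8 per degree of freedom.

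The 14441 cells formed 27 clusters, of which 24 could be named from fixed marker lists. Clusters with glial, neuronal or neuroblast markers are called glia, neurons and neuroblasts for short. Neuroblasts are the dividing stem cells of the brain. UMIs were summed per library and class, so that each comparison had n = 4 libraries per group. Levels are given as CPM, counts scaled to the library total, with the SD over 4 libraries, and log2 fold changes compare knockdown with control and carry their standard error (SE). Unless another method is named, adjusted p-values come from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment over all genes tested in a class.

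Ama itself (FBgn0000071, chromosome 3R 6762593 to 6765261 on the forward strand, 4 distinct annotated exons, in the Ensembl annotation of BDGP6.54) was lower in every knockdown library. In glia it stood at 921, 1313, 2083 and 1158 CPM in control replicates 1 to 4 and at 66.3, 47.8, 18.9 and 66.7 CPM in knockdown replicates 1 to 4. The log2 fold change was -4.71 ± 0.42 (SE), which is 26.1-fold lower, with an edgeR adjusted p of 5.4e-07. The values rest on 937 control and 11 knockdown UMIs. Over all retained cells Ama fell by 4.80 on the log2 scale (SE 0.40, edgeR adjusted p = 1.7e-06), and over all barcodes its mean level was 62.6 ± 22.3 CPM in control and 2.12 ± 0.98 CPM in knockdown libraries. Neurons held 13 control and 0 knockdown Ama UMIs and neuroblasts 10 and 0, too few to be tested, and the same was true of repo in both classes. The glial homeodomain gene repo (FBgn0011701) was also lower in glia, with 231 ± 45.1 CPM in control and 48.5 ± 44.9 CPM in knockdown libraries. Its log2 fold change was -1.63 ± 0.42 (edgeR adjusted p = 0.013), and leaving out knockdown replicate 3 gave -1.40 with an edgeR adjusted p of 0.066 (range over the alternatives 0.0026 to 0.066), while leaving out knockdown replicate 4 gave -2.72.

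In glia, the class in which the driver is active, 214 of 1527 genes tested changed, 130 upward and 84 downward. CG9691 was 88.5-fold, CG15784 63.1-fold and Arc1 44.6-fold higher. Over the alternatives the log2 fold changes ran from 5.57 to 7.56 for CG9691, 5.64 to 6.62 for CG15784 and 4.78 to 5.68 for Arc1. Arc1, which encodes a protein that forms virus-like capsids, rose from 132 ± 61.5 to 6060 ± 2730 CPM (log2 fold change 5.48 ± 0.38, edgeR adjusted p = 1.3e-08). CG15784 (FBgn0029766, X 5429571 to 5432526) rose from 38.1 ± 23.1 to 2676 ± 566 CPM (5.98 ± 0.35, edgeR adjusted p = 1.3e-09). The lactate dehydrogenase gene ImpL3, also called Ldh (FBgn0001258, 3L 6259105 to 6262694), was 24.0-fold higher (4.58 ± 0.49, edgeR adjusted p = 5.5e-06). Other large increases were those of the cuticle protein gene Cpr78E (5.05 ± 0.52), the glutathione transferase gene GstE6 (4.14 ± 0.45) and CG1572 (4.76 ± 0.88), the last of which gave 7.47 without control replicate 1. The non-coding gene CR44430 had 0 UMIs in control and 67 in knockdown glia, at least 86.9-fold higher against a floor of 3 counts over the group, or 45.4-fold without knockdown replicate 2 (edgeR adjusted p = 2.9e-05).

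The largest decreases in glia besides Ama included genes that were not detected after the knockdown. CG4476 had 143 UMIs in control and 0 in knockdown glia, at least 17.1-fold lower (edgeR adjusted p = 0.0010). CG31690, annotated as Tmtc1, had 117 and 0 UMIs, at least 12.1-fold lower (edgeR adjusted p = 1.9e-04). Eip78C, an ecdysone-induced nuclear receptor gene (FBgn0004865, 3L 21226609 to 21266503), had 105 control and 3 knockdown UMIs, 11.3-fold fewer per UMI sequenced (95% counting interval 3.77 to 55.8). Its fitted log2 fold change was -3.38 ± 0.63 (edgeR adjusted p = 0.0012), or -7.10 without knockdown replicate 4, the only knockdown library with any of its UMIs. CG6287 fell by 3.61 on the log2 scale (SE 0.56) and gave -7.99 without that library. CG14598 (-3.63 ± 0.69), CG42240 (-2.79 ± 0.47) and E(spl)m7-HLH, a repressor gene activated by Notch (-2.52 ± 0.52, edgeR adjusted p = 0.0024), were also lower.

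Of 12 tested genes of glycolysis and sugar transport, 7 rose and 0 fell in knockdown glia, both over all genes and adjusted over the list alone, and 5 did not pass. As a group they passed with a preset correlation (camera adjusted p = 8.1e-05) but not with an estimated one (camera adjusted p = 0.41 with an estimated correlation). Besides ImpL3, the aldolase gene Ald rose 5.81-fold (2.54 ± 0.29, edgeR adjusted p = 1.2e-05), the phosphoglucose isomerase gene Pgi 2.67-fold (1.41 ± 0.32) and Gapdh2 2.41-fold (1.27 ± 0.27). Of 8 unfolded protein and translation stress genes, 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.020, and 0.41 with an estimated correlation). Among them were Hsc70-3, the chaperone of the endoplasmic reticulum (2.14 ± 0.36, edgeR adjusted p = 5.7e-04), and the stress-induced transcription factor gene Atf3 (2.57 ± 0.36, edgeR adjusted p = 9.3e-05). Among 6 ecdysone response genes, 0 rose and 3 fell (4 adjusted over the list alone; camera adjusted p = 0.035, and 0.41 with an estimated correlation), led by Eip78C and by ImpE1 (-1.21 ± 0.26, edgeR adjusted p = 0.0034). Of 8 heat shock genes, which also respond to dissociation of tissue, 0 rose and 2 fell (4 adjusted over the list alone; camera adjusted p = 0.0046, and 0.41 with an estimated correlation). They were Hsp23 (-2.02 ± 0.36, edgeR adjusted p = 8.1e-04) and Hsp70Bc (-1.72 ± 0.41, or -2.72 without knockdown replicate 4), whose reads cannot be separated with certainty from near-identical Hsp70 copies.

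Of 9 receptor tyrosine kinase (RTK) target and feedback genes, 2 rose and 0 fell (3 adjusted over the list alone). As a group this list did not pass with camera in glia. The protease gene rho, which releases ligands of the epidermal growth factor receptor, rose 3.18-fold (1.67 ± 0.34, edgeR adjusted p = 0.0023). The feedback inhibitor gene sty had a log2 fold change of 0.72 ± 0.25 that did not pass (edgeR adjusted p = 0.061), although it did without knockdown replicate 4 (0.84, edgeR adjusted p = 0.036, range over the alternatives 0.036 to 0.52). Of 2 RTK ligand genes tested, bnl, encoding a fibroblast growth factor, rose from 23.2 ± 23.6 to 254 ± 149 CPM (3.41 ± 0.65, edgeR adjusted p = 0.0014). Among 4 RTK receptor and cascade genes 0 changed by edgeR, with 1 at an unadjusted p under 0.05 and 0 by DESeq2. Of 4 genes for proteins with immunoglobulin domains or their partners, 0 rose and 1 fell. It was Nrt, which encodes the Ama-binding protein Neurotactin, at -1.31 ± 0.37 (edgeR adjusted p = 0.024). Without control replicate 3, knockdown replicate 2 or knockdown replicate 3 the values of Nrt in glia were -1.03, -1.15 and -1.38, with edgeR adjusted p-values of 0.082, 0.056 and 0.054 (range over the alternatives 0.0044 to 0.082).

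Other fixed lists had few members with enough counts in glia. Of 3 cell death genes, 1 rose (1 up and 1 down adjusted over the list alone). This was Xrp1, a stress-responsive transcription factor gene (1.58 ± 0.21, edgeR adjusted p = 4.9e-05). Of 6 genes of the JNK and wound response, 3 rose, among them the glutathione transferase gene GstD1 (1.69 ± 0.30, edgeR adjusted p = 8.1e-04). GstD1 and GstE6 were also the 2 of 7 glutathione and oxidative stress genes that rose (2 up and 1 down adjusted over the list alone). Among 5 genes of glutamate, GABA and glutamine handling, 2 rose and 1 fell. Glutamine synthetase 2 (Gs2) rose 2.97-fold (1.57 ± 0.30, edgeR adjusted p = 0.0013), whereas glutamate dehydrogenase (Gdh) fell by 2.13 on the log2 scale (SE 0.49, edgeR adjusted p = 0.0056). E(spl)m7-HLH fell as 1 of 5 Notch targets, and 1 of 6 basement membrane genes, 1 of 2 synaptic genes and 1 of 12 mitochondrially encoded genes rose. The camera adjusted p of the cell death, JNK, glutathione, glutamate, Notch, basement membrane and mitochondrial lists ran from 0.058 to 0.85. By fry, which asks of each list by itself whether it changed, Notch targets passed as lower (fry adjusted p = 0.028).

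Besides the RTK receptors and cascade, no gene passed in the main test in 4 further glial lists. By edgeR 0 of 5 septate junction and blood-brain barrier genes, 0 of 3 cell cycle genes (1 up adjusted over the list alone), 0 of 3 engulfment genes and 0 of 2 lipid handling genes passed. DESeq2 called 0 in each, and 1, 1, 0 and 1 of them had an unadjusted p under 0.05. The septate junction gene cora had a log2 fold change of 0.81 ± 0.32 (edgeR adjusted p = 0.099, range over the alternatives 0.036 to 0.96), but 0.05 with classes from marker UMIs and 1.09 without knockdown replicate 4, where it passed. Of the cell cycle list, stg in glia passed with at least 200 genes per cell (1.39, edgeR adjusted p = 0.011, range over the alternatives 0.011 to 0.26), and of the lipid list, Npc2a in glia without a count filter (-1.22, edgeR adjusted p = 0.0067, range over the alternatives 0.0067 to 0.40). The engulfment receptor gene drpr had -0.26 ± 0.42 (edgeR adjusted p = 0.73). No immune effector gene had enough counts. Markers of other cell types gave no call in glia by edgeR or DESeq2. This held for 3 neuronal, 1 neuroblast, 2 neuroepithelial, 1 hemocyte and 1 muscle marker gene, of which 1 neuronal and 1 neuroepithelial marker had an unadjusted p under 0.05. Of 7 glial marker genes 1 rose and 1 fell, Gs2 and repo.

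**Figure D1:**
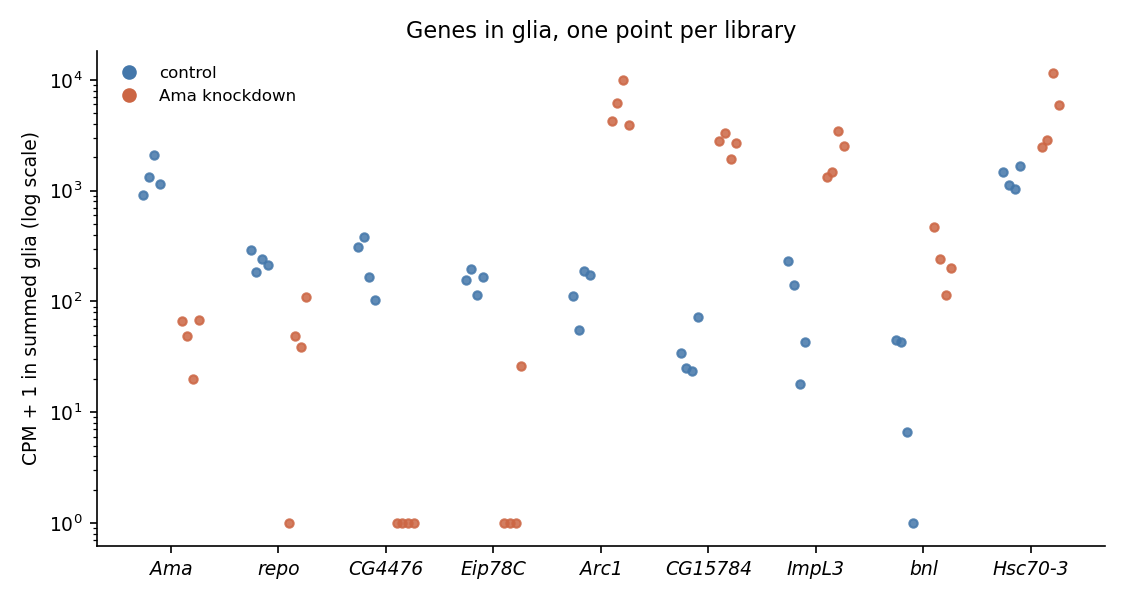
Levels of 9 genes in glia, with 1 point per library (4 control in blue, 4 knockdown in orange). The vertical log axis gives CPM + 1, so that a point at 1 marks a library without a UMI of the gene. The 4 knockdown libraries lie below the 4 control libraries for Ama, repo, CG4476 and Eip78C, and above them for the other genes.

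The glial counts rest on 428 control and 213 knockdown cells, with 19 and 25 cells in the 2 shallowest knockdown libraries. Control glia lay mostly in subclusters 0, 3, 4 and 1 and knockdown glia in subclusters 5, 6 and 1, so the comparison sets different mixes of glia against each other. In barcodes with under 100 UMIs, used here as a measure of free RNA, 176 of 193 genes called in glia had a change of the same sign (median absolute log2 fold change 0.848, against 1.397 in glia). Ama, Cpr78E and CG14598 were among the 10 leading genes of one glial cluster, Arc1, ImpE1 and Gs2 of another, and CG4476 of another one that held control cells alone, so the fall of CG4476 and the absence of those cells are one observation. Among subclusters, Cpr78E and CG1572 were leading genes of subcluster 5 (3 control and 93 knockdown cells). CG14598 was a leading gene of subcluster 2 (46 and 2) and E(spl)m7-HLH of subcluster 3 (99 and 17). The changes of these 4 genes are therefore not independent of the mix of glia. When glia were classed from marker UMIs alone, without clustering, the log2 fold changes in glia were 4.78 for Arc1 and -5.42 for Ama, and 90 of 755 genes tested changed.

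In neurons, in which the driver is not active, 973 of 4152 genes tested changed, 560 upward and 413 downward. A ribosomal RNA precursor, pre-rRNA:CR45845, was 10.5-fold higher. The nuclear receptor gene Hr38 was 9.36-fold higher (3.23 ± 0.34, edgeR adjusted p = 1.4e-07) and sr, the fly relative of mammalian early growth response genes, 7.39-fold higher (2.89 ± 0.24, edgeR adjusted p = 5.4e-09). The RNA-binding protein gene Imp, a regulator of neuroblast timing, rose from 1494 ± 589 to 9240 ± 3977 CPM (2.62 ± 0.31, edgeR adjusted p = 6.5e-07). The calcium-activated potassium channel gene slo (2.59 ± 0.25) and the calcium-binding protein gene Cbp53E (2.50 ± 0.23) also rose. The pigmentation gene y had 571 control and 2 knockdown UMIs, 98.4-fold fewer per UMI sequenced (95% counting interval 27.1 to 814). Its fitted log2 fold change was -6.23 ± 0.47 (edgeR adjusted p = 8.2e-10), or -9.53 without knockdown replicate 4. Over all barcodes y had 1516 control and 11 knockdown UMIs, so its near absence was not limited to neurons. Pigment genes such as y often mark fly strains and the labels do not give full genotypes, so this and other differences between the groups cannot be separated from a difference in genetic background.

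The ecdysone-regulated transcription factor genes Hr4 (-2.60 ± 0.45, edgeR adjusted p = 1.1e-04) and Eip74EF (-2.44 ± 0.29, edgeR adjusted p = 9.1e-07) were lower in neurons. The other large decreases were heat shock genes, Hsp67Bc (-2.15 ± 0.22, edgeR adjusted p = 6.3e-08), Hsp70Bc (-2.44 ± 0.28) and Hsp70Ab (-2.42 ± 0.38, or -4.21 without knockdown replicate 4), of which the Hsp70 copies share near-identical sequence. Of 12 heat shock genes 0 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 1.8e-06). With an estimated correlation that list did not pass (camera adjusted p = 0.38 with an estimated correlation).

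All 12 glycolysis and sugar transport genes tested in neurons rose, also adjusted over the list alone. They included ImpL3 (2.38 ± 0.26, edgeR adjusted p = 2.5e-07) and Ald (2.24 ± 0.23, edgeR adjusted p = 9.3e-08). The list had a camera adjusted p of 2.8e-14, and of 0.095 with an estimated correlation. With only clusters 0, 12 and 13, which had cells in every library, and these weighted alike, their median log2 change in raw CPM was 0.364 rather than 1.19. RTK target and feedback genes rose in 6 of 9 cases and fell in 0, also adjusted over the list alone. Examples were the ERK phosphatase gene Mkp3 (2.37 ± 0.24, edgeR adjusted p = 6.3e-08), Spred (1.20 ± 0.24, edgeR adjusted p = 5.2e-04) and sty (1.13 ± 0.25, edgeR adjusted p = 0.0018). Camera gave an adjusted p of 4.6e-04, and 0.49 with an estimated correlation. Synaptic genes rose in 7 of 14 cases and fell in 0 (8 adjusted over the list alone). Choline acetyltransferase (Cha, annotated as ChAT) rose by 1.52 ± 0.24 (edgeR adjusted p = 3.5e-05) and glutamate decarboxylase (Gad1) by 1.57 ± 0.26 (edgeR adjusted p = 7.1e-05). For this list the camera adjusted p was 6.3e-04, and 0.38 with an estimated correlation. Of 8 neuronal marker genes 6 rose and 0 fell (7 adjusted over the list alone; camera adjusted p = 6.8e-07, and 0.082 with an estimated correlation). The same list named the neuron clusters. Its mean log2 ratio was highest in cluster 13 (2.84), whose share of cells was 2.91% in control and 10.3% in knockdown libraries. The rise of these markers is therefore not independent of the mix of clusters.

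Ecdysone response genes of neurons moved both ways, with 2 of 12 up and 3 down (3 and 3 adjusted over the list alone). The nuclear receptor gene ftz-f1, which is expressed as ecdysone levels drop, rose 6.07-fold (2.60 ± 0.32, edgeR adjusted p = 1.6e-06), while Eip74EF fell. Unfolded protein and translation stress genes did the same, with 2 of 9 up and 2 down, among them Atf3 (2.01 ± 0.34) and CaBP1 (-1.38 ± 0.24). Of 7 RTK receptor and cascade genes 2 rose and 1 fell, and of 6 RTK ligand genes 1 rose, the Alk ligand gene jeb (1.33 ± 0.24, edgeR adjusted p = 1.9e-04). Of 5 JNK genes 2 fell, among them the JNK gene bsk itself (-0.99 ± 0.21, edgeR adjusted p = 0.0013). Of 6 septate junction genes 1 rose, the sodium pump gene Atpalpha (1.11 ± 0.23, edgeR adjusted p = 9.8e-04). Changes were also counted for cell death (1 up, 1 down of 4), cell cycle (2 up of 4), basement membrane (1 up of 2), glutamate handling (1 up, 1 down of 4), glutathione (1 down of 5) and immunoglobulin-domain genes (2 down of 10). Of 12 mitochondrially encoded genes 2 rose and 1 fell, mt:ND2 (1.22 ± 0.28) and mt:ATPase8 (-2.27 ± 0.41) among them. The cell death gene hid fell by 1.77 on the log2 scale in neurons (SE 0.46, edgeR adjusted p = 0.0063) but had 0.87 when neurons were classed from marker UMIs (edgeR adjusted p = 0.12, range over the alternatives 4.0e-04 to 0.12). All of these lists had a camera adjusted p of 0.11 or higher where it could be computed, while fry passed the RTK ligands as higher and the JNK and immunoglobulin-domain lists as lower (fry adjusted p = 0.039, 0.046 and 0.029). By edgeR 0 of 7 lipid handling, 0 of 5 Notch target and 0 of 2 engulfment genes changed, with 1, 3 and 1 at an unadjusted p under 0.05 and 0 by DESeq2.

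The neuronal comparison set different mixes of clusters against each other. Control neurons lay mostly in clusters 0, 3, 12, 15 and 8, and knockdown neurons in clusters 0, 13 and 12. Cbp53E, sr, jeb and slo were among the 10 leading genes of cluster 13, so their rise and the mix of clusters are not independent. The same holds for the fall of Hsp67Bc, a leading gene of cluster 15, which held 464 control and 9 knockdown cells. With neurons limited to clusters 0, 12 and 13, which had at least 5 cells in every library, and summed together, 783 of 3458 genes changed. The mix still differed within that sum, as cluster 0 held 720 control and 533 knockdown cells and cluster 13 held 288 and 371. Tested singly, clusters 0, 12 and 13 had 469, 225 and 572 changed genes. In barcodes with under 100 UMIs 761 of 792 genes called in neurons had a change of the same sign, with a median absolute log2 fold change of 0.775 against 0.951 in neurons. Without knockdown replicate 3 the count in neurons was 552 rather than 973.

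In neuroblasts 815 of 4014 genes tested changed, 509 upward and 306 downward. Arc1 rose here too, from 2.12 ± 0.76 to 124 ± 68.0 CPM (5.77 ± 0.46, edgeR adjusted p = 5.8e-07), on 6 control and 213 knockdown UMIs. In barcodes with under 100 UMIs Arc1 stood at 200 CPM in control and 1798 CPM in knockdown libraries. The transcription factor gene fru was 13.4-fold higher (3.74 ± 0.36, edgeR adjusted p = 3.7e-06). CG13957, annotated as SWIP (3.58 ± 0.35), CG6191 (3.17 ± 0.34) and the myosin light chain kinase gene Strn-Mlck (3.25 ± 0.67) were among the other large increases, with the ribosomal RNA precursor pre-rRNA:CR45845 (4.41 ± 0.42). The homeobox gene scro (-2.09 ± 0.28, edgeR adjusted p = 4.7e-05) and slp2, a forkhead gene of the temporal series of optic lobe neuroblasts (-1.87 ± 0.23, edgeR adjusted p = 2.5e-05), were lower. So were l(3)87Df (-2.53 ± 0.31), the long non-coding RNA pncr002:3R (-2.48 ± 0.27) and CG13920 (-1.95 ± 0.24).

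Of 22 cell cycle and DNA replication genes tested in neuroblasts 0 rose, 7 fell and 15 did not pass (1 up and 7 down adjusted over the list alone), and the camera adjusted p was 4.1e-04, or 0.080 with an estimated correlation. The DNA replication inhibitor gene geminin fell by 1.45 on the log2 scale (SE 0.25, edgeR adjusted p = 6.7e-04) and the mitotic kinase gene Cdk1 by 1.17 (SE 0.22, edgeR adjusted p = 0.0012). RTK target and feedback genes rose in 7 of 11 cases and fell in 0, also adjusted over the list alone. The transmembrane feedback gene kek1 rose 6.33-fold (2.66 ± 0.26, edgeR adjusted p = 3.7e-06) and sty 2.66-fold (1.41 ± 0.27, edgeR adjusted p = 0.0012). With camera the adjusted p was 3.9e-04, and 0.38 with an estimated correlation. Of 11 glycolysis genes 4 rose and 0 fell (7 adjusted over the list alone), with Ald at 2.42 ± 0.34 (edgeR adjusted p = 7.8e-05) and Gapdh1 at 2.02 ± 0.28 (edgeR adjusted p = 8.5e-05). Its camera adjusted p was 4.1e-04, and 0.38 with an estimated correlation.

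Ecdysone response, synaptic and heat shock lists passed in neuroblasts with the preset correlation (camera adjusted p = 0.034, 0.020 and 0.032) but not with an estimated one (camera adjusted p = 0.38, 0.38 and 0.41 with an estimated correlation). Of 8 ecdysone response genes 2 rose, among them the receptor gene EcR (2.21 ± 0.24, edgeR adjusted p = 7.2e-06). Of 6 synaptic genes 3 rose, among them the calcium channel gene cac (1.71 ± 0.25, edgeR adjusted p = 1.4e-04), which had 0.93 in cells with at least 600 genes (edgeR adjusted p = 0.10, range over the alternatives 1.8e-09 to 0.10). Of 9 heat shock genes 1 rose and 5 fell, among them Hsp70Bc (-2.21 ± 0.39) and Hsp23 (-1.43 ± 0.26, edgeR adjusted p = 8.8e-04). Counts of these 3 lists were the same adjusted over the list alone. Of 5 neuronal marker genes 4 rose in neuroblasts and 0 fell (camera adjusted p = 0.015, and 0.39 with an estimated correlation).

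The remaining neuroblast lists had a camera adjusted p of 0.069 or higher or too few members for it. By fry the septate junction and lipid handling lists passed as higher and the unfolded protein list as lower (fry adjusted p = 0.016, 0.0095 and 0.0084). Single members rose in the cell death list (Xrp1, 1.61 ± 0.24, 1 of 4), the JNK list (GstD1, 1.55 ± 0.27, 1 of 5) and the RTK ligands (1 of 2), and 1 of 6 RTK receptor and cascade genes fell. Lipid handling genes rose in 2 of 4 cases, with fatty acid synthase (CG3523, annotated as FASN1) at 1.54 ± 0.32, and septate junction genes in 2 of 6, with Atpalpha at 0.87 ± 0.21. Both glutamate handling genes tested changed, and Gdh rose by 2.36 ± 0.33 (edgeR adjusted p = 8.4e-05). Changes in both directions were counted for basement membrane (1 up, 1 down of 3), mitochondrially encoded (3 up, 1 down of 12) and glutathione genes (2 up, 1 down of 8). GstS1, of the last list, fell by 1.90 on the log2 scale in neuroblasts (SE 0.37, edgeR adjusted p = 0.0014) and had -0.44 with classes from marker UMIs (edgeR adjusted p = 0.23, range over the alternatives 2.3e-05 to 0.23). Of 8 unfolded protein genes 1 fell, and 1 of 4 genes of the immunoglobulin-domain list, Nrt (-0.84 ± 0.18, edgeR adjusted p = 0.0025). By edgeR 0 of 9 Notch target and 0 of 2 engulfment genes changed, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Cluster 11, with CycE, RnrS, Mcm7 and slp2 among its leading genes, held 516 control and 346 knockdown neuroblasts, against 484 and 520 in cluster 7 and 82 and 173 in cluster 21, so the falls of cell cycle genes and of slp2 are not independent of the mix of clusters. In barcodes with under 100 UMIs 620 of 651 genes called in neuroblasts had a change of the same sign, with a median absolute log2 fold change of 0.703 against 0.998 in neuroblasts. The count of 815 fell to 498 without control replicate 3, to 478 without knockdown replicate 3 and to 513 without the 2 shallowest libraries.

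Over all retained cells, a comparison that needs no clustering but includes changes in cell mix, 1976 of 7117 genes changed, 1111 upward and 865 downward. CG15784 (4.76 ± 0.25, edgeR adjusted p = 2.5e-08), Arc1 (4.49 ± 0.25, edgeR adjusted p = 2.7e-08), ImpL3 (3.62 ± 0.29, edgeR adjusted p = 1.0e-06) and the DNA damage response gene Gadd45 (3.48 ± 0.23, edgeR adjusted p = 1.2e-07) led the increases, with the ribosomal RNA precursor pre-rRNA:CR45845 (3.75 ± 0.32). CG42502 (-3.94 ± 0.33), Hr4 (-3.63 ± 0.36), l(3)87Df (-2.99 ± 0.26), Hsp70Bc (-2.67 ± 0.39) and Hsp67Bc (-2.57 ± 0.22) led the decreases. Across all cells sty rose 2.06-fold (1.05 ± 0.23, edgeR adjusted p = 0.0044) and repo fell by 1.39 on the log2 scale (SE 0.38, edgeR adjusted p = 0.014). Over all barcodes the raw level of sty was 400 ± 75.7 CPM in control and 526 ± 60.6 CPM in knockdown libraries, with overlap (313 to 490 and 475 to 613). In neuroepithelium sty had raw levels of 844 ± 142 and 829 ± 196 CPM, so its rise was not shared by every class. Of 14 glycolysis genes 12 rose and 0 fell (13 adjusted over the list alone). This was the only gene list of any class that passed with an estimated correlation (camera adjusted p = 2.8e-11, and 0.012 with an estimated correlation). Of 12 Notch targets 0 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 1.8e-04, and 0.43 with an estimated correlation). Heat shock genes rose in 1 and fell in 6 of 12 cases (1 and 7 adjusted over the list alone; camera adjusted p = 1.8e-04, and 0.43 with an estimated correlation). RTK targets rose in 6 of 12 cases (7 adjusted over the list alone; camera adjusted p = 0.0014, and 0.55 with an estimated correlation). The single immune effector gene with enough counts rose, and the other 16 gene lists had a camera adjusted p of 0.065 or higher. Of these, fry passed the RTK ligand, glutamate handling, glutathione and unfolded protein lists as higher and the immunoglobulin-domain list as lower (fry adjusted p = 0.0086, 0.032, 0.039, 0.012 and 0.032). Marker genes of newborn neurons and ganglion mother cells, the cells that divide last before neurons form, fell in 5 of 5 cases (camera adjusted p = 1.4e-04, and 0.030 with an estimated correlation).

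The other marker lists over all cells had a camera adjusted p of 0.072 or higher, or too few members for it. No hemocyte (0 of 2), fat body (0 of 1), muscle (0 of 1) or trachea (0 of 3) marker changed by edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Over all barcodes, however, the hemocyte marker Hml had 17 control and 50 knockdown UMIs, against 10 and 17 in retained cells. Its raw levels over all barcodes were 0 to 1.39 CPM in control and 2.08 to 6.04 CPM in knockdown libraries, without overlap but on small counts. No ring gland marker had enough counts. The 1 photoreceptor marker tested rose, as did 4 of 8 neuronal, 2 of 7 neuroblast, 1 of 8 glial and 1 of 6 neuroepithelial markers, while 1 glial and 1 neuroepithelial marker fell. Among glial subtype markers 1 of 4 cortex, 1 of 3 astrocyte-like and 1 of 3 perineurial genes rose, and 2 of 4 ensheathing and 1 of 3 perineurial genes fell. By edgeR and DESeq2 0 of 5 subperineurial and 0 of 3 wrapping glial markers changed, with 1 and 0 at an unadjusted p under 0.05. The camera adjusted p of the subtype lists was 0.96.

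**Figure D2:**
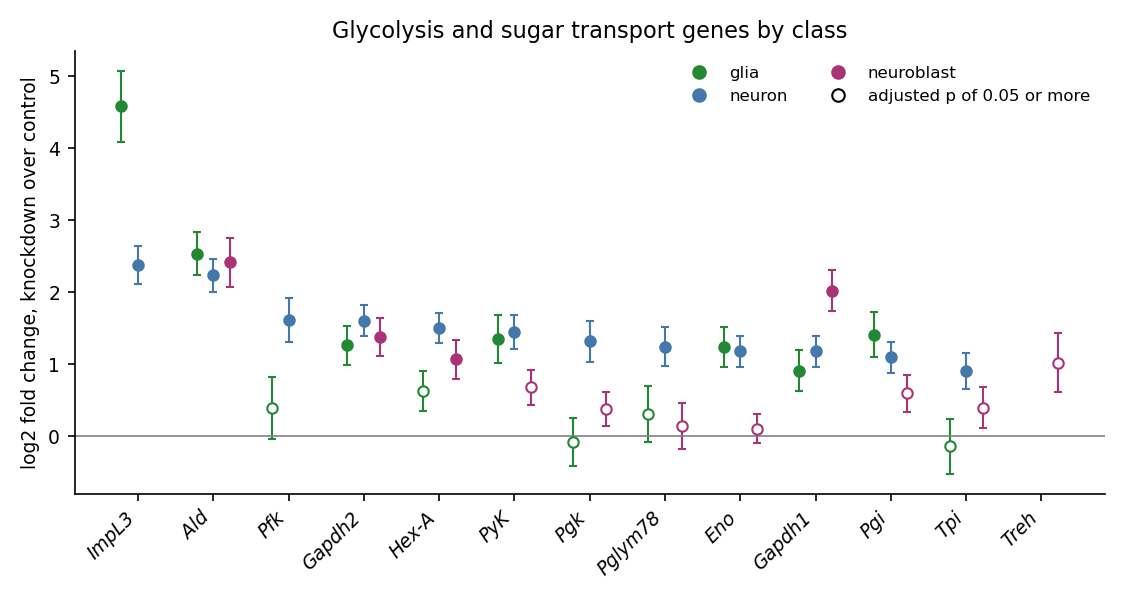
Log2 fold changes of glycolysis and sugar transport genes in glia (green), neurons (blue) and neuroblasts (purple), with bars for the SE from fits to 4 against 4 libraries. Open points mark an edgeR adjusted p of 0.05 or more, and a gene without a point in a class had too few counts there. All 12 genes tested in neurons lie above 0 with filled points.

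Whether the knockdown effect differed between glia and neurons was tested as an interaction, with the library as a term. Of 2949 genes, 246 differed, 81 with a higher and 165 with a lower change in glia. These numbers were 116 and 146 with limma voom. Without the perineurial-like glia and with neurons of clusters present in every library they were 116 and 113, so the excess of lower changes depends on the method and the cells used. The difference for Arc1 was 3.05 ± 0.33 on the log2 scale (edgeR adjusted p = 2.2e-16), as Arc1 went from 127 ± 60.9 to 4763 ± 2200 CPM in glia and from 24.4 ± 12.9 to 100 ± 62.0 CPM in neurons of the joint fit. RhoGAP18B (4.62 ± 0.93, edgeR adjusted p = 5.1e-05) and the malic enzyme gene Men (2.97 ± 0.45, edgeR adjusted p = 1.6e-08) also had higher changes in glia. Gdh differed the other way, down in glia and up in neurons (-3.38 ± 0.55, edgeR adjusted p = 1.6e-07). It went from 175 ± 49.5 to 21.7 ± 27.2 CPM in glia and from 41.2 ± 13.5 to 69.3 ± 36.1 CPM in neurons of the joint fit. Its rise in neurons did not pass under every alternative. CG31690 had 0 UMIs in knockdown glia and 56.1 ± 15.2 CPM in knockdown neurons, and its fitted difference of -8.83 ± 1.38 depends on the prior count (edgeR adjusted p = 5.9e-08). CG15309 (edgeR adjusted p = 0.0070) and salm (edgeR adjusted p = 0.023) were likewise absent from knockdown glia, so their fitted differences also depend on the prior count. The call was lost for CG15309 without knockdown replicate 4 (-6.80, edgeR adjusted p = 0.099, range over the alternatives 0.0084 to 0.099). It was lost for salm without control replicate 4 (-5.45), knockdown replicate 3 (-6.46) or knockdown replicate 4 (-6.67), with edgeR adjusted p-values of 0.11, 0.088 and 0.12 (range over the alternatives 0.019 to 0.12).

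CG15784 had a difference of 5.23 ± 0.84 between glia and neurons (edgeR adjusted p = 1.6e-07), but its neuronal level was only 3.35 ± 6.13 CPM in control libraries. Leaving out control replicate 2 gave 2.78 with an edgeR adjusted p of 0.70 (range over the alternatives 2.0e-09 to 0.70), and leaving out knockdown replicate 4 gave 8.86. CG1572 in glia minus neurons had 4.61 ± 1.46 (edgeR adjusted p = 0.026). It lost the call without control replicate 3 (4.17), control replicate 4 (3.58), knockdown replicate 1 (4.33) or knockdown replicate 3 (4.07), with a highest edgeR adjusted p of 0.31 (range over the alternatives 0.0018 to 0.31), and gave 8.64 without control replicate 1 and 7.60 without knockdown replicate 4. CG9413, a leading gene of the perineurial-like glia, had -3.18 ± 0.38 (edgeR adjusted p = 1.7e-13) but 3.29 when those glia were left out and neurons were limited to clusters present in every library (edgeR adjusted p = 0.0016, the highest of its alternatives, the lowest being 6.3e-16). For Ama (-1.41 ± 2.89, edgeR adjusted p = 0.86), repo (-2.63 ± 1.96, edgeR adjusted p = 0.52) and sty (-0.52 ± 0.23, edgeR adjusted p = 0.16) the difference between the classes did not pass in the main test, with near-absent neuronal counts for Ama and repo. With limma voom the differences of Ama in glia minus neurons and repo in glia minus neurons did pass (-4.05 and -4.14, limma adjusted p = 0.0015 and 9.6e-04), and that of sty in glia minus neurons did with clusters that had cells in every library (-0.96, edgeR adjusted p = 0.0017), so these 3 depend on the method or the cells used. Without knockdown replicate 3 the count of 246 was 154.

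Shares of cell classes were compared per library with exact permutation tests over 70 relabellings, for which 0.0286 is the smallest possible two-sided p. Neuroblasts made up 10.9 ± 1.21% of control and 24.7 ± 2.50% of knockdown cells, higher in 4 of 4 knockdown libraries (exact permutation p = 0.0286, 0.11 adjusted over the 4 planned classes). Glia made up 4.29 ± 0.25% and 5.12 ± 0.83% (exact permutation p = 0.11, adjusted 0.23), neurons 32.8 ± 1.68% and 32.2 ± 3.64% (exact permutation p = 0.94, adjusted 0.94). Hemocytes, blood cells seen as 8 control and 26 knockdown cells, made up 0.079 ± 0.071% and 0.40 ± 0.35% (exact permutation p = 0.23, adjusted 0.30). Among classes that were not planned, newborn neurons and ganglion mother cells made up 30.7 ± 2.97% of control and 8.35 ± 3.85% of knockdown cells, and neuroepithelium, the progenitor sheet of the optic lobe, 12.6 ± 1.24% and 24.7 ± 3.28% (exact permutation p = 0.0286 each, 0.057 adjusted over 6 classes). With marker UMIs in place of clusters the neuroepithelial shares were 2.57 ± 0.97% and 1.82 ± 0.66% (exact permutation p = 0.29). Those of newborn neurons and ganglion mother cells were then 7.61 ± 2.53% and 1.49 ± 1.16% (exact permutation p = 0.0286), a difference of -6.11 rather than -22.4 percentage points. Control neuroepithelium lay mostly in clusters 5, 23 and 17 and knockdown neuroepithelium in clusters 17 and 25. Clusters of neuroblasts and of neuroepithelium had leading genes that changed between the groups, such as slp2 in a neuroblast cluster and ImpL3 and Gadd45 in cluster 25, so these shares are not independent of the gene changes. With marker UMIs in place of clusters neuroblasts made up 19.8 ± 0.68% of control and 27.7 ± 3.95% of knockdown cells (exact permutation p = 0.0286), a difference of 7.85 rather than 13.8 percentage points.

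**Figure D3:**
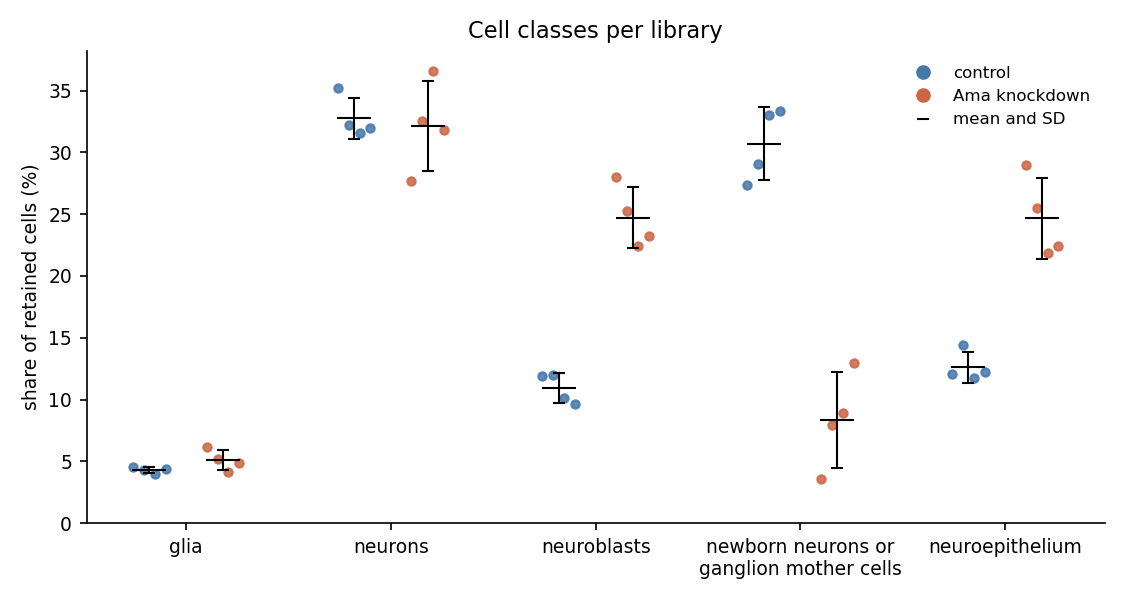
Share of retained cells in 5 classes, with 1 point per library (4 control in blue, 4 knockdown in orange) and the mean and SD over 4 libraries in black, on a linear axis in percent. All 4 knockdown libraries lie above all 4 control libraries for neuroblasts and neuroepithelium, and below them for newborn neurons and ganglion mother cells.

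Among glia, a subcluster named from perineurial markers held control cells alone. Its name rests on 3 enriched perineurial markers, none of them among its 10 leading genes. Perineurial glia form the outer layer of the blood-brain barrier. There were 76 cells in it of 428 control glia and 0 of 213 knockdown glia, which allows a share of up to 1.41% by a floor of 3 cells (exact upper limit 1.72%). The control share was 18.02 ± 3.95% (12.7 to 22.2% per library, exact permutation p = 0.0286, 0.043 adjusted over 3 named subtypes). Single knockdown libraries held only 19 to 117 glia, so that 0 cells in replicates 1 to 4 allows 15.8, 12.0, 5.77 and 2.56% each. Leading genes of this subcluster, CG4476 and CG9413, changed between the groups, and Jupiter, the only fixed perineurial marker with enough counts in glia, fell there by 1.42 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0014). Glia held only 1162 of the 27508 control UMIs of Jupiter. Over all barcodes Jupiter went from 1321 ± 59.0 to 694 ± 132 CPM, so its fall was not particular to perineurial cells. Other perineurial markers were still present in knockdown glia, with 15 control and 6 knockdown UMIs of CG6126, 26 and 18 of Indy, and 55 and 25 of Tret1-1, from 761982 and 246493 glial UMIs. Per UMI sequenced, none of CG6126, Indy and Tret1-1 was lower in knockdown than in control glia, although these counts are small.

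A subcluster called cortex-like, after the glia that enwrap neuronal cell bodies, made up 1.30 ± 1.15% of control and 30.02 ± 15.3% of knockdown glia (exact permutation p = 0.0286, adjusted 0.043). At double the subclustering resolution the difference was 7.99 rather than 28.7 percentage points (exact permutation p = 0.0857, adjusted 0.129), and at the lowest resolution no cortex-like subcluster was named. There the subcluster that matched the cortex list best stayed unnamed, because a marker of another subtype was among its leading genes. That subcluster made up 28.8 ± 2.59% of control and 33.8 ± 4.71% of knockdown glia (exact permutation p = 0.20), so the cortex-like difference depends on how the cells were split. The name rests on 4 enriched cortex markers, none of them among the 10 leading genes, which include the fat body marker Rfabg. Leading genes such as Arc1 rose in knockdown glia, so the share is not independent of those changes. Astrocyte-like glia made up 2.16 ± 2.64% and 2.78 ± 3.65% (exact permutation p = 0.74, adjusted 0.74).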

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

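The tests of other splits of the libraries, of free RNA for glycolysis, of clusters within each class and of the perineurial-like subcluster were chosen after those results had been seen, and the other tests of this part before their values were computed.

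Single libraries stood apart from the other 3 of their group in 24 of 368 groups of values screened (6.52%), and chance alone marks about 1 in 20. In glia, CR44430 was at 1004 CPM in knockdown replicate 2 (others 133 to 267), Cpr78E at 700.1 CPM in knockdown replicate 4 (191 to 265) and Cg25C at 478 CPM in knockdown replicate 2 (66.3 to 100). CG1572 stood at 44.4 CPM in control replicate 1, where the other controls had 0, and at 663 CPM in knockdown replicate 1 (100 to 191). CG31690 was low in control replicate 1 at 122 CPM (178 to 188), and kek1 high there at 743 CPM (377 to 425). CG14598 stood at 56.7 CPM in knockdown replicate 3 (0 to 8.33), and CG6287 at 41.7 and Eip78C at 25.0 CPM in knockdown replicate 4, where the other knockdowns had 0. PCNA was at 0 CPM in glia of knockdown replicate 1 (170 to 191), drpr at 199 CPM there (94.5 to 100), and Atpalpha at 2079 CPM in knockdown replicate 3 (1100 to 1260).

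In neurons y was at 3.07 CPM in knockdown replicate 4 (others 0) and Atpalpha at 3138 CPM in the same library (4495 to 4697), and control replicate 1 had the highest neuron share at 35.2% (31.6 to 32.2). In neuroblasts control replicate 1 was high for sty at 425 CPM (168 to 206), slp2 at 310 CPM (248 to 258) and Lsd-2 at 42.7 CPM (30.9 to 32.5). EcR was at 52.8 CPM in control replicate 2 (32.2 to 34.7), CG13920 at 109 CPM in knockdown replicate 4 (72.1 to 74.0) and GstD1 at 102 CPM in knockdown replicate 3 (217 to 226). Over all cells ImpL3 was low in knockdown replicate 1 at 230 CPM (381 to 386) and Gadd45 high in control replicate 3 at 14.0 CPM (12.4 to 12.6).

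The effect of the knockdown differed between glia and neurons for 246 genes by the interaction test. The named differences on the log2 scale were 5.23 for CG15784, 4.62 for RhoGAP18B, 4.61 for CG1572, 3.05 for Arc1 and 2.97 for Men. With a lower change in glia they were -8.83 for CG31690, -6.80 for CG15309 (fitted -6.805), -6.40 for salm, -3.38 for Gdh and -3.18 for CG9413. CG31690, CG15309 and salm had 0 CPM in knockdown glia, so the size of their fitted differences depends on the prior count. The difference of CG15784 was 2.78 without control replicate 2 (edgeR adjusted p = 0.70, range over the alternatives 2.0e-09 to 0.70) and 8.86 without knockdown replicate 4. CG1572 in glia minus neurons lost its call without control replicate 3 (4.17), control replicate 4 (3.58), knockdown replicate 1 (4.33) or knockdown replicate 3 (4.07), and gave 8.64 without control replicate 1 and 7.60 without knockdown replicate 4. CG15309 lost it without knockdown replicate 4 (-6.80), and salm without control replicate 4 (-5.45), knockdown replicate 3 (-6.46) or knockdown replicate 4 (-6.67).

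Barcodes with under 100 UMIs were left out of the gene tests of the report, and several genes were higher there in the knockdown than in control libraries. Arc1 and CR43283, chosen after their values were seen, stood at 1797.5 and 130200 CPM in the knockdown and at 200 and 34203 CPM in control libraries. The precursor pre-rRNA:CR45845 went from 167 to 1293 CPM.

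Chance in how the libraries fell into groups can be excluded at the 5% level as the source of the numbers of changed genes. Among the 35 splits of 8 libraries into 4 and 4, only 1, the real one, gave as many changed genes in each of the comparisons. The real split gave 214 genes in glia against at most 1 in another split, 973 in neurons against 1, 815 in neuroblasts against 0, 1976 in all cells against 0 and 246 for the interaction against 6.

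Glycolytic genes were higher in 3 classes at once, which could come from free RNA shared by all droplets. Their rise in CPM was a median 8.57 times that in barcodes with under 100 UMIs for the 7 genes called in glia and 4.20 times for the 12 in neurons (1.06 to 44.95 for 10 genes, with 2 that did not rise in free RNA counted as highest), which argues against free RNA there, but 0.885 in neuroblasts with 2 of 4 genes above 1, so it remains open for neuroblasts. With clusters that had cells in every library weighted alike the 4 called genes of neuroblasts had a median log2 change of 0.816 rather than 1.35, with a mean level higher in every knockdown library and 2 of 4 genes without overlap, which argues against a changed mix of clusters as the whole cause there, although 1 cluster had a list median of 0.171. In glia the median was 1.25 (lowest cluster 0.206), but 0 of 9 subclusters had at least 5 cells in every library, so a changed mix of glia stays open. In neurons a changed mix stays open, because the median was 0.364 with clusters weighted alike and 1.19 without. Of the 12 genes 11 were then still above 0 and 3 had no overlap between libraries, but their mean level overlapped between the groups. Cluster 13 (8 of 12 genes up, list median 0.957) also differed from cluster 0 (0 of 6, -0.219). The bound set in advance, a median of 0.5 over single clusters, was met at 0.595 with 9 of 10 above 0 but pooled the classes and so was too loose for neurons. The 2 shallowest libraries do not carry the result, since 21 of 23 called genes stayed called without them, and a metabolic response of the brain to loss of Ama in glia remains possible but was not tested.

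The perineurial-like subcluster held no knockdown glia. Too few glia is not enough to explain this, since 0 of 213 allows 1.41% by a floor of 3 cells (exact upper limit 1.72%) and the lowest control library had 12.7%. Whether the cells were present without their defining genes stays open, because only 1 of 5 fixed perineurial markers had enough counts to be tested in glia, while CG6126, Indy and Tret1-1 kept 6, 18 and 25 UMIs in knockdown glia. Per UMI sequenced, CG6126, Indy and Tret1-1 were not lower in knockdown than in control glia. Over all barcodes CG6126 stood at 2.86 CPM in control and 3.18 in knockdown libraries, Indy at 5.73 and 5.93, Tret1-1 at 10.9 and 10.3, Jupiter at 1321 and 694, and CG4476 had 212 and 2 UMIs (62.4-fold fewer, 95% counting interval 17.1 to 519). Loss of the cells, a change of their expression and a change in how well they survive dissociation are therefore not told apart.

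Arc1 RNA was more abundant in barcodes with under 100 UMIs than in retained cells, 12.3-fold in control and 6.09-fold in knockdown libraries. Free RNA from broken glia would enrich other glial genes as much, and the highest ratio among the 20 most glia-enriched genes in control was 7.12. A general excess of abundant transcripts would give like ratios at like levels. Of control genes within 2-fold of the level of Arc1 in cells, 0.0% had as high a ratio. However, Arc1 was chosen after its values were seen and had the highest ratio of 5577 genes in control. Both outcomes were thus fixed in advance, and they cannot decide either explanation. Such ratios were not limited to Arc1, since pre-rRNA:CR45845 had 11.6 in control and 8.50 in knockdown libraries and CG13337 had 9.07 in the latter. What sets these transcripts apart stays open, and no biological explanation was tested.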

How the results depend on the processing

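Named genes kept direction and side of the threshold in 1729 of the values under alternatives other than leaving out a library, became called in 30, lost the call in 90 and reversed in 19. With single libraries left out, 1329 stayed, 12 became called, 114 lost the call and 15 reversed. Where a value moved, the cause was not tested unless said. Reversals were stg in neurons (-0.13 with classes from marker UMIs, -0.23 at resolution 0.75), hid in neurons (0.87, marker UMIs) and CG9413 between glia and neurons (3.29 with clusters in every library, chosen after seeing the data). The others changed sign in glia without being called before or after. Without a count filter PCNA in glia had -0.19 and ImpL2 in glia -0.22. With marker UMIs PCNA in glia had -0.14 and Lsd-2 in glia 0.43. With 200 genes PCNA in glia had -0.22. With doublets kept PCNA in glia had -0.21, Atpalpha in glia 0.10 and Lac in glia 0.0629. Lac in glia had 0.0032 at resolution 0.75 and 0.0050 at 3. Without the perineurial-like subcluster PCNA in glia had -0.0504 and Lsd-2 in glia 0.10, and without the 2 shallowest libraries Cg25C in glia had -0.21, ImpL2 in glia -0.48 and Lac in glia 0.10 (both chosen after seeing the data). With 1 library left out the ranges were -0.0281 to 0.44 for InR in glia, -0.50 to 0.10 for csw in glia, -0.11 to 0.18 for PCNA in glia, -0.55 to 0.0485 for ced-6 in glia, -0.19 to 0.80 for Cg25C in glia, -0.00966 to 0.58 for BM-40-SPARC in glia, -1.01 to 0.34 for wrapper in glia, -0.31 to 0.35 for ImpL2 in glia and -0.12 to 0.10 for Lac in glia. Counts of changed genes moved by over 1.5 times in glia from 214 to 341 without a count filter (more genes tested) and 90 with marker UMIs (755 genes tested). They moved in neuroblasts from 815 to 513 without the 2 shallowest libraries (fewer samples, chosen after seeing the data) and in all cells from 1976 to 1233 with 600 genes per cell. The share of glia differed by 0.83 percentage points, by -1.46 with 600 genes, -0.12 with marker UMIs and 1.15 with doublets kept (exact permutation p = 0.0286). That of neurons differed by -0.58, by 6.56 with 200 genes (exact permutation p = 0.0571) and -18.4 with 600 genes (exact permutation p = 0.0286, the smallest possible). That of neuroblasts differed by 13.8 and by 15.9 with 600 genes (exact permutation p = 0.0571). Of glial subtypes 2 passed, 1 at subclustering resolution 0.3 and 0 at 1.2, where cortex-like glia differed by 7.99 percentage points (exact permutation p = 0.0857). The perineurial-like difference was -18.02 at every resolution, and its call at 1.2 was lost through the adjustment alone (exact permutation p = 0.0286, adjusted 0.0857). At 1.2 an unnamed subcluster of 0 control and 38 knockdown cells matched the perineurial list best, but with only 1 enriched marker. Of gene lists 18 of 72 passed with camera, 1 with an estimated correlation and 30 with fry. With 1 library left out counts ran from 151 to 253 in glia, 552 to 1208 in neurons, 478 to 1016 in neuroblasts, 1323 to 2194 in all cells and 154 to 258 for the interaction, each with fewer samples. Ama in glia ran from -5.29 to -4.41. Differences in share ran from 0.478 to 1.15 for glia, -2.05 to 0.910 for neurons, 12.7 to 14.5 for neuroblasts, 0.214 to 0.455 for hemocytes, -19.8 to -16.6 for perineurial-like and 24.1 to 34.2 for cortex-like glia. With 600 genes per cell no sums were possible for glia or neurons, and no hemocyte cluster was found with 200 or 600. Depth limits the glial test to 1527 genes.

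The replicate number as a block gave 185 changed genes in glia, 830 in neurons, 752 in neuroblasts and 1824 in all cells, and 17 lists. Libraries with the same number did not all deviate together (correlations in glia 0.211, 0.0711, -0.0041 and -0.0335), so the numbers are not taken as pairs.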

Other observations

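Genes of this part were chosen after their values were seen. The non-coding RNA gene CR43283, annotated as cherub, made up 1.72% of cell UMIs in control and 7.11% in knockdown libraries, in neuroblasts 5.64 and 14.4%, and in barcodes with under 100 UMIs 3.42 and 13.02%. Its log2 fold change in neuroblasts was 1.76 ± 0.24 (edgeR adjusted p = 7.5e-05), and free RNA as a source of that rise is not excluded. Imp, known from early stages of neuroblast lineages, rose in neuroblasts by 3.09 ± 0.41 (edgeR adjusted p = 4.7e-05). Its target chinmo, a transcription factor of early-born neurons, rose by 1.49 ± 0.25 in neuroblasts (edgeR adjusted p = 4.2e-04) and 3.28 ± 0.26 in neuroepithelium (edgeR adjusted p = 2.4e-08). The late factor Eip93F fell in neurons by 1.94 on the log2 scale (SE 0.33, edgeR adjusted p = 1.2e-04) and had -5.92 in neuroepithelium (SE 0.46, edgeR adjusted p = 2.4e-08), with 0.50 in neuroblasts (edgeR adjusted p = 0.14). The late RNA-binding factor Syp also rose in neuroblasts (1.46 ± 0.20, edgeR adjusted p = 6.5e-05) and fell in glia (-1.32, edgeR adjusted p = 0.0031). Syp was a leading gene of neuroblast cluster 21, whose share of cells rose from 0.80 to 6.04%, and CR43283 one of cluster 7 (4.88 to 11.1%), so their rise in neuroblasts is not independent of the mix of clusters.

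In neuroepithelium, a comparison added after the data had been seen, 856 of 3590 genes changed, 490 upward and 366 downward. The insulin-binding protein gene ImpL2 rose by 4.11 ± 0.30 (edgeR adjusted p = 1.2e-08) and the cell death gene hid by 2.20 ± 0.28 (edgeR adjusted p = 1.0e-05). ImpL3 (4.38), Gadd45 (4.00) and CG15784 (3.86) rose there too, and all 5 genes were leading genes of cluster 25, so they restate that cluster, which held 3 control and 262 knockdown cells. Control neuroepithelium lay mostly in clusters 5, 23 and 17 and knockdown neuroepithelium in 17 and 25. In newborn neurons and ganglion mother cells 282 of 2515 genes changed, 125 upward and 157 downward, but 0 clusters of this class had at least 5 cells in every library, so that comparison sets different cells against each other.

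The pigment gene y, commonly used as a strain marker, was almost absent from the knockdown. The labels do not give full genotypes, so a difference in genetic background cannot be separated from the knockdown in any comparison. Over all barcodes y had 1516 control and 11 knockdown UMIs (71.8 and 0.671 CPM). The pigment gene w rose in glia by 2.62 ± 0.30 on the log2 scale in the edgeR test, where it was a leading gene of a subcluster of 3 control and 93 knockdown cells. Over all barcodes its libraries overlapped (40.2 to 49.3 CPM in control, 38.8 to 115.3 in knockdown), so w is not shown to differ across cells.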
